A study of Danio rerio with 15 samples.

How the data were processed

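Poly(A) RNA-seq was measured in kdrl-positive cells from zebrafish embryos at 28 hours post fertilization, in 15 libraries of 6 groups, which combined 3 genotypes (wildtype, sibling, sf3b1 mutant) with 2 Stat3 constructs (wildtype or constitutively active). Each genotype had 2 libraries with WT-Stat3 and 3 with CA-Stat3. Per the labels' protocols, RNA came from a microprep kit, was primed with oligo dT and was made into low-input libraries. Groups and replicate numbers were taken from the sample titles, and 0 columns of the table lacked a sample.

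The deposited table held whole-number counts per Ensembl gene, not normalized, with 1 column per library. Per the submitters' processing notes, which give no roles or order, the tools were Trim Galore, STAR 2.4.2a, Picard, featureCounts and DESeq2, and the build was GRCz10. The annotation release, strand setting, duplicate handling and treatment of multi-mapping reads are not given in the sources used here, so counts of near-identical paralogs, overlapping genes and antisense pairs are uncertain. The counts do not show splicing, so intron retention and splice site use were not analysed here. No coordinates were used. Of 32105 gene identifiers, 26269 had a symbol in the gene name table used here and 5836 had none, and 1632 symbols were shared by several identifiers, which are told apart by identifier where needed. Symbols are printed as that table gives them, some in capitals. Library totals were 3625121 to 8170371 counts. The labels name no molecular identifiers, so floors of 3 counts and the intervals of pooled ratios cover counting error only.

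Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group with a minimum count of 10 and a minimum total of 15, which left 18020 of the 27820 genes with any count. Libraries were scaled by TMM, and 1 model with a coefficient per group was fitted over all 15 libraries with a shared estimate of the spread and 9 residual degrees of freedom. The quasi-likelihood test (glmQLFit and glmQLFTest) gave 11 comparisons, with Benjamini-Hochberg (BH) adjustment over genes and a threshold of 0.05. These were mutant minus wildtype, sibling minus wildtype and mutant minus sibling averaged over constructs, mutant minus wildtype in each construct, CA-Stat3 minus WT-Stat3 averaged over genotypes and in each genotype, and the interaction of construct with the mutant or sibling genotype. Standard errors of log2 fold changes were approximated as the absolute log2 fold change over the square root of the F statistic. Log2 CPM used a prior count of 2.

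The comparisons, tests, gene lists, named-gene rule and most other settings were fixed before the data were examined. The 23 gene lists covered pathways, endothelial identities, stress genes and markers of other cell types that a kdrl sort could hold, and 2 of them were defined by symbol pattern. Lists were tested by camera with a preset correlation of 0.01 between genes and BH adjustment over the lists of a comparison, beside camera with an estimated correlation and fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes. Adjusted over the list alone means BH adjustment over the tested members of that list. The counts of lists called cover all 23, and the values of 1 pathway list and its members are not reported here. Lists shared few genes, the most being 12 between arterial and Notch lists and 6 between STAT3 target and immediate-early lists. Exact permutation tests of list means across libraries, 10000 random lists matched on expression and the tests of symbol families were not among the tests fixed beforehand.

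Genes were named by rule. SF3B1, STAT3 and kdrl were always named. For the mutant and construct averages the 5 genes with the largest change in each direction were named, and for other comparisons 3, among those with an adjusted p under 0.05, an average log2 CPM of at least 1, no overlap between the libraries of the 2 genotypes or constructs within a stratum, and a symbol that is not a clone or predicted locus. For each list up to 3 called members with the smallest p were named, and best-known members could be named with their values. Genes outside the rule are said to have been chosen after their values were seen, and uncalled genes named beside a count of 0 were also chosen after their values were seen.

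The other settings fixed beforehand were DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), RLE size factors, no filter, a stricter filter (1 CPM in 5 libraries and a total of 50), own libraries only, a replicate block and leaving out each library. Chosen after seeing the data were leaving out both outlying libraries, thinning all libraries to the total of the shallowest, leaving out the 3 most abundant rows, and leaving out each library for the list tests and cross-construct correlations. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the other groups. Tests were tried first on simulated counts drawn from the real means, library sizes and spread, with 200 genes changed by known folds. For the mutant average over 17574 simulated genes, edgeR recovered 10.8% of 1.5-fold, 41.5% of 2-fold and 83.1% of 4-fold changes, with 7 false calls among 95. The real mutant comparison called 28.7% of genes, far more than were changed here, so these rates may be too low for it. For the mutant interaction over 17496 simulated genes it recovered 1.52% of 2-fold and 45.5% of 4-fold changes, with 6 false calls among 37. Camera called the changed list and 0 of 20 unchanged lists in each of these simulations. The simulated genes varied independently of each other, so this did not test camera on lists of correlated genes. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.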

Results

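The data were poly(A) RNA-seq counts from kdrl-positive cells of zebrafish embryos at 28 hours post fertilization. The kdrl gene encodes a vascular endothelial growth factor receptor, so these cells are mainly endothelial. Embryos were wildtype, sf3b1 mutant, or siblings of the mutants whose sf3b1 alleles the labels do not give. Sf3b1 is the core subunit of the SF3b complex, the part of the spliceosome that recognises the branch point of introns. All embryos overexpressed Stat3, a transcription factor of cytokine signalling, either as the wildtype protein (WT-Stat3) or in a constitutively active form (CA-Stat3), and no library without overexpression was used here. The 15 libraries fell into 6 groups, with 2 libraries for each genotype with WT-Stat3 and 3 for each genotype with CA-Stat3. The labels do not say whether replicates came from separate clutches or sorts, so p-values measure the spread between these libraries, which may be partly technical.

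Total counts were 6212802 to 8170371 in the 5 wildtype libraries, 5161557 to 8059498 in the 5 sibling libraries and 3625121 to 6506853 in the 5 mutant libraries. The row zgc:158463 alone held 16.3% to 39.5% of a library's counts, the highest share being in replicate 2 of the mutant WT-Stat3 group. That library was also the shallowest and stood apart from all others on the first principal component. Spearman correlations of log2 CPM (counts scaled to the library total after TMM normalization) within groups were 0.918 to 0.967 over 12 pairs, and mutant libraries correlated with wildtype or sibling libraries at 0.824 to 0.945 over 50 pairs.

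The mutated gene itself was measured in every library to check the labels. SF3B1 (ENSDARG00000056138) had 96.2 ± 10.6 CPM in mutants (SD, n = 5), 164 CPM in siblings (n = 5) and 193 ± 15.3 CPM in wildtypes (SD, n = 5). The 5 mutant libraries lay between 82 and 108 CPM and no wildtype or sibling library lay below 157 CPM. SF3B1 fell by 0.97 ± 0.11 (log2, SE) in mutants against wildtypes, a ratio of 0.509 (edgeR BH-adjusted p = 1.76e-05), and by 0.76 ± 0.11 against siblings (edgeR BH-adjusted p = 0.000199). SF3B1 in siblings was at -0.21 ± 0.11 against wildtypes and was not called (edgeR BH-adjusted p = 0.567). Within each construct, however, every sibling library lay below every wildtype library. The values were 157 and 167 against 170 and 185 CPM with WT-Stat3, and 157 to 172 against 198 to 208 CPM with CA-Stat3. STAT3 (ENSDARG00000022712) ranged from 162 to 468 CPM and differed between constructs by -0.08 ± 0.20 (edgeR BH-adjusted p = 0.903), and the counts do not separate endogenous from introduced transcripts. The sorted gene kdrl (ENSDARG00000105215) ranged from 329 to 884 CPM, with a mutant minus wildtype value of 0.18 ± 0.19 (edgeR BH-adjusted p = 0.501) and a CA-Stat3 minus WT-Stat3 value of -0.31 ± 0.15 (edgeR BH-adjusted p = 0.413).

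**Figure D1:**
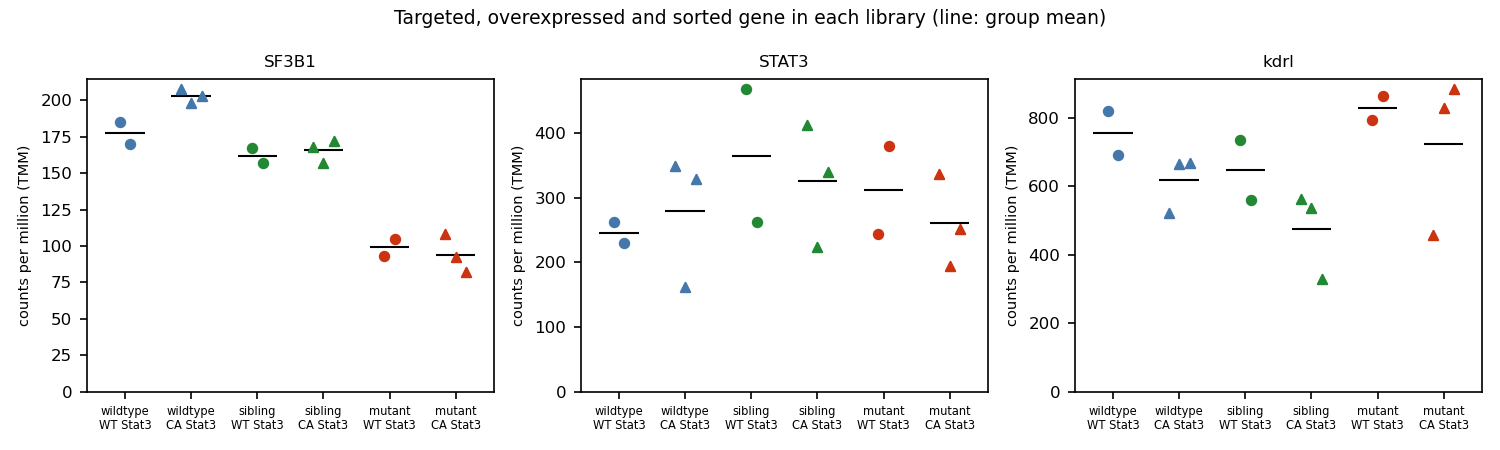
TMM-scaled CPM of SF3B1, STAT3 and kdrl in each of the 15 libraries, by genotype and Stat3 construct, where circles are WT-Stat3 libraries, triangles are CA-Stat3 libraries and lines are group means. The 5 mutant libraries sit between 82 and 108 CPM for SF3B1, below all wildtype and sibling libraries, while STAT3 and kdrl overlap between groups.

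The main question was how loss of sf3b1 function altered the transcriptome of these cells, and the mutant minus wildtype difference averaged over both constructs addressed it. By camera, mutant cells had raised transcripts of the splicing machinery, and lowered transcripts of macrophage, neutrophil, connective tissue and neural genes. With an estimated correlation none of these lists was called, at adjusted p = 0.0869 for splicing, 0.162 for macrophage and neutrophil and for connective tissue, and 0.692 for neural genes, whose 15 calls became 3 without replicate 2 of the mutant WT-Stat3 group. The genes with the largest increases were RSPO1 (4.66 ± 0.55), which encodes a Wnt signalling enhancer, ARMC2 (4.47 ± 0.54), ATXN1 (4.33 ± 0.29), PDE6D (4.1 ± 0.31), and brf2 (3.93 ± 0.27), an RNA polymerase III initiation factor. RSPO1 and ARMC2 had only 15 and 10 counts over the 5 wildtype libraries, so their sizes and ranks are uncertain. The largest decreases were in crybb1l1 (-6.84 ± 0.95), a lens crystallin with 2 counts over the 5 mutant libraries (pooled ratio 77.4, 95% exact Poisson counting interval 21.2 to 643), shtn2 (-5.89 ± 1.17), fcer1g (-5.43 ± 0.88), an adaptor of immune receptors, ccl35.1 (-4.66 ± 1.06), a chemokine, and cfh (-4.56 ± 0.64), complement factor H. crybb1l1, shtn2 and fcer1g had 0 counts in both mutant WT-Stat3 libraries, so their averages and ranks are not exact. The smallest adjusted p of all belonged to snapc4, a subunit of the complex that starts transcription of spliceosomal small nuclear RNA genes, which rose by 3.62 ± 0.15 (edgeR BH-adjusted p = 4.99e-10), and was chosen after its value was seen. Of 18020 genes tested, edgeR with BH adjustment called 5169, of which 2502 were higher and 2667 lower in mutants, and 2710 of them differed by over 2-fold. ccl35.1 lost its call without replicate 2 of the wildtype WT-Stat3 group, at -3.47 (edgeR BH-adjusted p = 0.0729).

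Of 99 spliceosome components tested, 66 were higher, 4 lower and 29 not called in mutants (68 higher and 5 lower adjusted over the list alone), with a list median of 0.82. The list was called by camera (BH-adjusted p = 1.27e-39) but not with an estimated correlation between genes (adjusted p = 0.0869 with an estimated correlation). PRPF31, a tri-snRNP assembly factor, rose by 3.17 ± 0.15 from 27.7 ± 2.55 CPM in wildtypes to 251 ± 53.8 CPM in mutants (SD, n = 5 each). SNRNP200, a helicase of the spliceosome, rose by 2.67 ± 0.13 and EFTUD2, its partner GTPase, by 2.68 ± 0.14, each with an edgeR BH-adjusted p of at most 3.26e-09. Among 10 SF3a and SF3b subunits, a grouping chosen after the values were seen, 9 rose and SF3B1 fell by 0.97. The largest rise was in SF3A3 (2.09 ± 0.14) and the smallest in SF3B5 (0.53 ± 0.18, edgeR BH-adjusted p = 0.0396). SF3B5 lost its call without replicate 1 (0.60) or 2 (0.40) of the wildtype WT-Stat3 group, replicate 1 of the mutant WT-Stat3 group (0.41), replicate 1 (0.54), 2 (0.50) or 3 (0.54) of the wildtype CA-Stat3 group, and replicate 2 (0.52) or 3 (0.51) of the mutant CA-Stat3 group. Of 14 nonsense-mediated decay factors, 3 were higher (3 adjusted over the list alone), namely EIF4A3 (1.56 ± 0.14), SMG9 (0.91 ± 0.20) and CASC3 (0.49 ± 0.13), and camera did not call the list (median 0.22, BH-adjusted p = 0.0621). Across libraries, without comparison to other genes, the list mean rose by 0.25 ± 0.05 (exact permutation test over 120 splits, adjusted p = 0.0383). CASC3 lost its call without replicate 2 of the wildtype WT-Stat3 group, at 0.40 (edgeR BH-adjusted p = 0.072).

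Cell cycle genes went both ways, with 5 of 52 higher and 7 lower (3 and 5 adjusted over the list alone) and a median of -0.03 (camera BH-adjusted p = 0.65). Lower members were TOP2A (-0.90 ± 0.13), HMGB2 (-0.96 ± 0.18) and RRM2 (-1.50 ± 0.30). The 12 cell cycle calls became 7 without replicate 2 of the mutant WT-Stat3 group and 6 without either wildtype WT-Stat3 replicate, replicate 1 or replicate 2.

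Genes of non-endothelial cell types moved in both directions. Of 35 macrophage and neutrophil genes, 0 were higher and 30 lower (1 and 32 adjusted over the list alone). The median was -1.95 (camera BH-adjusted p = 8.92e-19, adjusted p = 0.162 with an estimated correlation). The granulocyte protease npsn fell by 3.99 ± 0.43, from 527 ± 151 to 37.8 ± 29.4 CPM, lysozyme (lyz) by 3.39 ± 0.39, from 511 ± 133 to 59.7 ± 42.2 CPM, and srgn by 2.11 ± 0.24 (SD of CPM, n = 5 each). Of 41 mesenchymal, notochord and cartilage genes, 0 were higher and 25 lower (1 and 26 adjusted over the list alone). The median was -1.09 (camera BH-adjusted p = 1.05e-09, adjusted p = 0.162 with an estimated correlation). The collagen COL1A1 fell by 2.47 ± 0.27, COL1A2 by 1.96 ± 0.24 and the receptor PDGFRA by 1.80 ± 0.24. Erythroid genes rose: 15 of 25 were higher and 0 lower (18 and 0 adjusted over the list alone). The median was 1.28 (camera BH-adjusted p = 1.88e-09, adjusted p = 0.431 with an estimated correlation). They included tfr1a (2.07 ± 0.28), FECH (1.68 ± 0.22) and blf (1.66 ± 0.23), and gata1a, the erythroid master regulator and the list's best-known gene, at 2.06 ± 0.30.

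Neural, muscle and epidermal genes had numbers of calls that depended on single libraries. Neural genes had 0 of 40 higher and 15 lower (0 and 16 adjusted over the list alone). The median was -0.57 (camera BH-adjusted p = 0.000179, adjusted p = 0.692 with an estimated correlation), led by NEUROD4 (-2.61 ± 0.35), ascl1a (-2.00 ± 0.40) and neurog1 (-3.13 ± 0.69). The 15 calls became 3 without replicate 2 of the mutant WT-Stat3 group, 7 without replicate 1 of the wildtype WT-Stat3 group, and 9 without replicate 1 of the wildtype CA-Stat3 group or replicate 3 of the mutant CA-Stat3 group. Of 36 muscle genes, 2 were higher and 6 lower (2 and 5 adjusted over the list alone). The median was -0.96 (camera BH-adjusted p = 0.0213, adjusted p = 0.754 with an estimated correlation). tpm1 fell by 1.31 ± 0.29, myhb rose by 1.03 ± 0.28 and TNNT2 fell by 1.45 ± 0.43. The 8 muscle calls became 1 without replicate 1 of the wildtype WT-Stat3 group, 3 without replicate 2 of the mutant WT-Stat3 group, 5 without replicate 2 of the wildtype CA-Stat3 group, and 4 without replicate 2 of the wildtype WT-Stat3, replicate 1 of the mutant WT-Stat3, or replicate 2 or 3 of the mutant CA-Stat3 group. myhb was not called without replicate 1 of the wildtype (0.77) or of the mutant (0.84) WT-Stat3 group, and TNNT2 was not called without replicate 1 of the wildtype (-1.30) or replicate 2 of the mutant (-1.20) WT-Stat3 group. Of 31 epidermal genes, 2 were higher and 10 lower (2 and 10 adjusted over the list alone). The median was -0.50 (camera BH-adjusted p = 0.0259, adjusted p = 0.692 with an estimated correlation), with pfn1 at -1.77 ± 0.25, apoeb at 1.41 ± 0.22 and krt91 at -1.39 ± 0.36. The 12 epidermal calls became 4 without replicate 2 of the mutant WT-Stat3 group and 7 without replicate 1 of the wildtype WT-Stat3 group, where krt91 lost its call (-1.13).

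STAT3 target, stress response and immediate-early genes were tested as 3 lists. Of 37 STAT3 target and feedback genes, 2 were higher and 13 lower in mutants (2 and 14 adjusted over the list alone). The median was -0.35 (camera BH-adjusted p = 0.00615, adjusted p = 0.162 with an estimated correlation). SOCS3 (ENSDARG00000026611), the feedback inhibitor of the pathway, fell by 1.69 ± 0.17 from 252 ± 18.8 to 83 ± 28.4 CPM (SD, n = 5 each), CEBPB by 1.82 ± 0.27, and the phosphatase PTPN6, also a leukocyte gene, by 1.95 ± 0.32, while the kinase jak2a rose by 1.08 ± 0.18 and was chosen after its value was seen. Of 45 integrated stress and unfolded protein response genes, 4 were higher and 19 lower (5 and 22 adjusted over the list alone). The median was -0.40 (camera BH-adjusted p = 0.00615, adjusted p = 0.42 with an estimated correlation), with the amino acid transporter subunit slc3a2a at -1.64 ± 0.21, the serine synthesis enzyme PHGDH at -1.97 ± 0.28 and CHAC1 at -1.15 ± 0.17. Those 23 calls became 14 without replicate 2 of the mutant WT-Stat3 group. Of 49 immediate-early and heat-shock genes, 8 were higher and 24 lower (9 and 26 adjusted over the list alone). The median was -0.50 (camera BH-adjusted p = 0.0145, adjusted p = 0.692 with an estimated correlation). Split by symbol after the values were seen, the list moved in 2 directions. Of 17 heat-shock and haem oxygenase genes 8 were higher and 0 lower by edgeR, with the chaperones HSPA8 (ENSDARG00000037403) at 3.38 ± 0.27 and HSPH1 at 1.91 ± 0.20, and of 32 immediate-early genes 0 were higher and 24 lower by edgeR, with the transcription factor egr1 at -1.44 ± 0.33.

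Translation and mitochondrial genes were tested as 2 lists. Of 88 genes matching the ribosomal protein name pattern, 4 were higher and 26 lower (4 and 32 adjusted over the list alone). The median was -0.27 (camera BH-adjusted p = 0.000143, adjusted p = 0.692 with an estimated correlation), with RPL12 at -0.99 ± 0.12 and RPL5 at -0.93 ± 0.14. The pattern also took in 10 genes that are not ribosomal proteins by their symbols, kinases and the ribosome assembly factor RPL7L1 (1.06 ± 0.17), and without them 1 of 78 was higher and 25 were lower. The 30 calls became 55 without replicate 1 and 15 without replicate 2 of the mutant WT-Stat3 group. Of 13 mitochondrially encoded genes, 5 were higher and 0 lower (6 and 0 adjusted over the list alone). The median was 0.44 (camera BH-adjusted p = 0.0139, adjusted p = 0.692 with an estimated correlation), with the cytochrome oxidase subunits MT-CO1 at 0.70 ± 0.12 and MT-CO3 at 0.52 ± 0.15, and MT-CYB at 0.67 ± 0.18. MT-CO3 and MT-CYB lost their calls without replicate 2 of the wildtype WT-Stat3 group (0.42 and 0.53) or replicate 1 of the mutant WT-Stat3 group (0.22 and 0.38). The 5 calls became 1 without replicate 2 of the wildtype WT-Stat3 or replicate 1 of the mutant WT-Stat3 group, 8 without replicate 2 of the mutant WT-Stat3 group, and 3 without replicate 2 or 3 of the wildtype CA-Stat3 group or of the mutant CA-Stat3 group.

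Endothelial genes were tested as 5 lists, of which camera called 1. Of 32 pan-endothelial genes, 3 were higher and 7 lower (3 and 7 adjusted over the list alone); the median was 0.03, the mean -0.08 and camera tested downward without a call (BH-adjusted p = 0.592). The best-known members were near 0, with cdh5 at -0.25 ± 0.17 and FLI1 at 0.19 ± 0.15, while the scavenger receptor MRC1 fell by 1.85 ± 0.18, robo4 by 0.58 ± 0.13, and the transcription factor TAL1 rose by 1.37 ± 0.25. The 10 calls became 6 without replicate 1 of the wildtype WT-Stat3 group or replicate 2 of the mutant WT-Stat3 group. Of 19 venous and lymphatic genes, 1 was higher and 6 lower (2 and 8 adjusted over the list alone). The median was -0.34 (camera BH-adjusted p = 0.0253, adjusted p = 0.692 with an estimated correlation), with stab1 at -0.82 ± 0.16 and DAB2 (ENSDARG00000053091) at 1.12 ± 0.17. TAL1 is also an erythroid regulator and may follow the erythroid list (median 1.28). MRC1 and stab1 could follow the macrophage list (-1.95) if macrophages of these embryos express them, which was not tested. The next 3 lists were not called. Of 32 arterial genes, 4 were higher and 7 lower (4 and 9 adjusted over the list alone). The median was -0.14 (camera BH-adjusted p = 0.224). Of 25 haemogenic endothelium and blood stem cell genes, 3 were higher and 4 lower (3 and 4 adjusted over the list alone). The median was 0.03 (camera BH-adjusted p = 0.787). Of 40 Notch pathway genes, 3 were higher and 9 lower (4 and 11 adjusted over the list alone). The median was -0.12 (camera BH-adjusted p = 0.208). Named members were ALPL (-1.33 ± 0.22), LTBP1 (-1.04 ± 0.20) and HLX (-1.49 ± 0.31) for arteries, GFI1B (2.94 ± 0.29), ptprc (-2.40 ± 0.35) and kitb (2.66 ± 0.47) for blood stem cells, where GFI1B is also an erythroid and ptprc a leukocyte gene, and RBPJ (-1.25 ± 0.16), adam10b (-0.76 ± 0.13) and ADAM17 (0.94 ± 0.18) for Notch.

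Interferon-stimulated genes (20 tested, 2 higher, 4 lower, 5 and 6 adjusted over the list alone; median -0.13, camera BH-adjusted p = 0.82), yolk and liver genes (19 tested, 3 higher, 1 lower, 3 and 1; median 0.47, camera BH-adjusted p = 0.334) and pronephric genes (20 tested, 2 higher, 3 lower, 2 and 3; median -0.23, camera BH-adjusted p = 0.724) were not called. isg15 rose by 2.42 ± 0.52, irf3 fell by 1.77 ± 0.46 and trim25 fell by 2.43 ± 0.54. apoc1 rose by 2.52 ± 0.54 but was not called without replicate 1 of the mutant WT-Stat3 group (1.65), as was atp1a1a.5 (2.45 ± 0.56, 1.62 without it), while ctsla fell by 0.88 ± 0.19, lhx1a fell by 1.78 ± 0.41 and SLC20A1 rose by 0.54 ± 0.13. Camera thus called 14 of the 23 lists, 4 upward and 10 downward, fry called 11, and camera with an estimated correlation called 0, its smallest adjusted p being the 0.0869 of the spliceosome list.

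**Figure D2:**
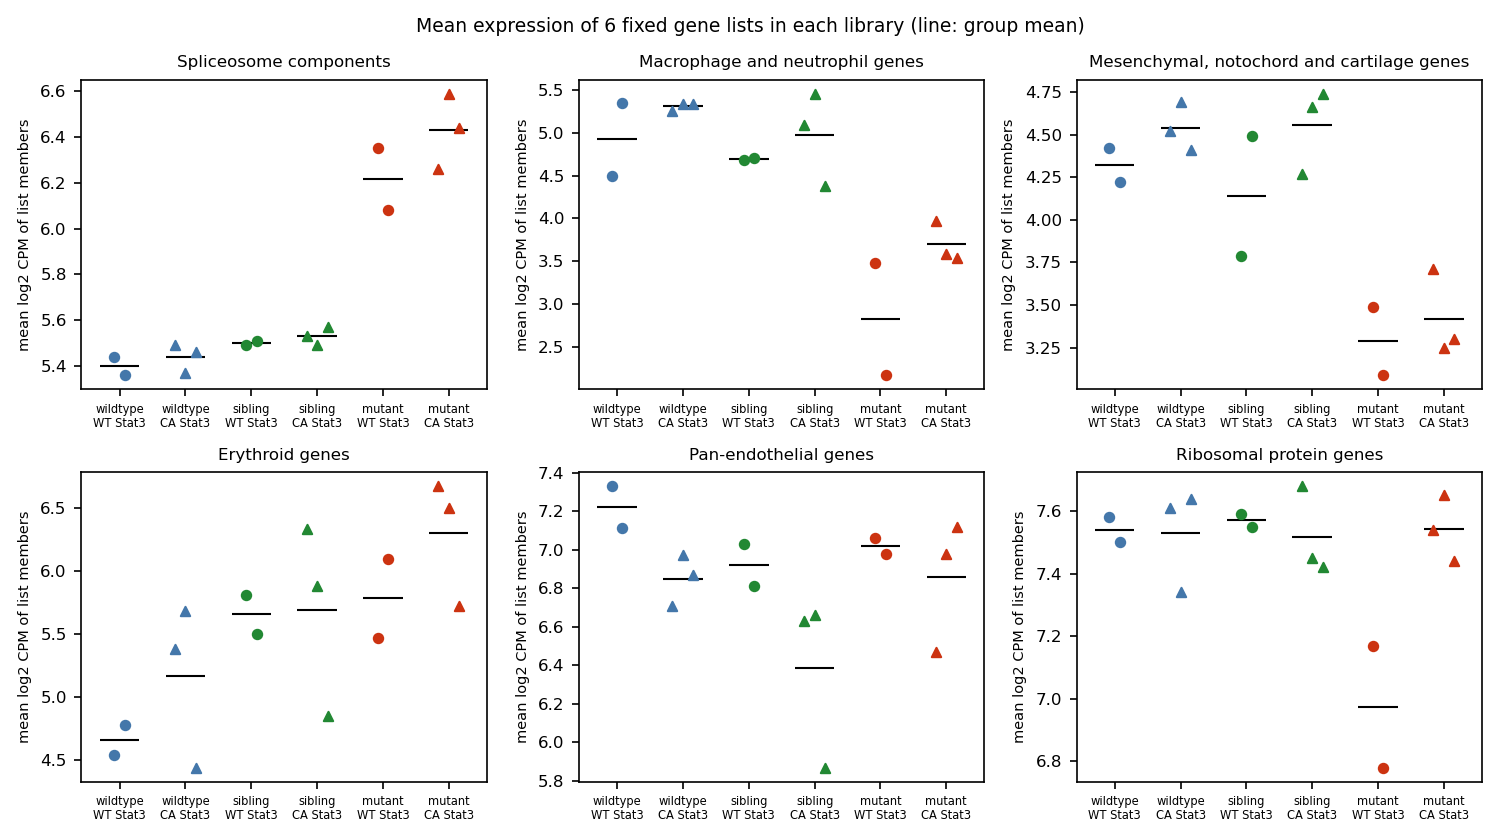
Mean log2 CPM of the members of 6 fixed gene lists in each of the 15 libraries, by genotype and construct, where circles are WT-Stat3, triangles are CA-Stat3 and lines are group means. Spliceosome means are higher and macrophage and neutrophil and mesenchymal means lower in the 5 mutant libraries than in wildtype libraries, while the ribosomal means of the mutant WT-Stat3 libraries lie below those of the mutant CA-Stat3 libraries.

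Mutants were also compared with their own siblings. Mutant cells had higher splicing transcripts and lower leukocyte, neural and connective tissue transcripts than sibling cells. Camera called 12 lists, but with an estimated correlation it called 0 (adjusted p = 0.124 to 0.723 with an estimated correlation for the 12). Of the lists, 61 of 99 spliceosome genes were higher and 5 lower (65 and 5 adjusted over the list alone; median 0.73), and 0 of 35 macrophage and neutrophil genes were higher and 26 lower (0 and 29; median -1.46). PRPF31 rose by 3.08 ± 0.15, while npsn fell by 3.52 ± 0.42 and COL1A1 by 2.25 ± 0.27. Neural genes were 0 of 40 higher and 25 lower (0 and 30; median -1.17) and mesenchymal genes 0 of 41 higher and 24 lower (1 and 25; median -1.24). edgeR with BH adjustment called 4729 genes, 2229 higher and 2500 lower. Of the genes named next, RSPO1 and cysltr3 had only 8 and 12 counts over the 5 sibling libraries. ccl35.1 had only 9 over the 5 mutant libraries, so the sizes and ranks of these genes are uncertain. The largest changes were RSPO1 (5.48 ± 0.62), LNX1 (4.38 ± 0.41), cysltr3 (4.35 ± 0.46), crybb1l1 (-7.57 ± 0.90, pooled ratio 120 with a 95% counting interval of 33 to 995 from the same 2 counts), ccl35.1 (-5.31 ± 0.98) and the muscle calcium buffer pvalb1 (-5.01 ± 1.08), which was not called without replicate 2 of the sibling WT-Stat3 group (-2.66, edgeR BH-adjusted p = 0.188). Without replicate 2 of the sibling WT-Stat3 group, 7 lists were called.

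Other lists called for mutants against siblings moved with single libraries, and none was called with an estimated correlation. Muscle genes were 1 of 36 higher and 21 lower (1 and 26 adjusted over the list alone; median -2.03). The 21 became 1 without replicate 2 of the sibling WT-Stat3 group (median -0.64) and 5 without replicate 2 of the mutant WT-Stat3 group (-1.58). Muscle means were 6.13 and 2.73 log2 CPM in the sibling WT-Stat3 libraries and 4.03 and 2.30 in the mutant ones, so without the higher sibling library mutants did not lie lower with WT-Stat3. Pan-endothelial genes were 12 of 32 higher and 1 lower (14 and 2; median 0.32). The 12 became 7 without replicate 1 and 5 without replicate 2 of the sibling WT-Stat3 group, 6 without replicate 2 and 7 without replicate 3 of the mutant CA-Stat3 group, and 7 with 5 lower (median 0.19) without replicate 3 of the sibling CA-Stat3 group. Ribosomal protein genes were 3 of 88 higher and 31 lower (3 and 34; median -0.30). The 31 became 13 without replicate 1 and 19 without replicate 2 of the sibling WT-Stat3 group, 51 and 10 without replicates 1 and 2 of the mutant WT-Stat3 group, 15 without replicate 1 of the sibling CA-Stat3 group, and 20 and 13 without replicates 2 and 3 of the mutant CA-Stat3 group. Erythroid genes were 9 of 25 higher and 1 lower (10 and 1; median 0.43, or 0.67 without replicate 1 and 0.24 without replicate 3 of the sibling CA-Stat3 group). Cell cycle genes were 2 of 52 higher and 13 lower (2 and 13; median -0.14, or -0.23 without replicate 1 of the sibling and -0.24 without replicate 1 of the mutant WT-Stat3 group). Stress response genes were 2 of 45 higher and 14 lower (2 and 16; median -0.30), and 9 were lower without replicate 2 of the mutant WT-Stat3 group. Mitochondrially encoded genes were 3 of 13 higher (4 and 0; median 0.33), and 1 was without replicate 2 of the sibling or replicate 1 of the mutant WT-Stat3 group, and 5 were without replicate 2 of the mutant WT-Stat3 group.

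Siblings were compared with wildtypes to ask whether the siblings already differed. edgeR called no single gene, and of the lists erythroid and neural genes tested upward and endothelial genes downward by camera. These list calls were lost with an estimated correlation, at adjusted p = 0.268 to 0.596 with an estimated correlation for the 14 lists called. edgeR with BH adjustment called 0 of 18020 genes, the smallest adjusted p being 0.0791 for SIK1 (-0.96 ± 0.15), with 1712 genes at an unadjusted p under 0.05, and DESeq2 called 12 and limma-voom 0. With no filter on expression, edgeR called 258 genes, all of which pass the filter, and with the replicate block it called 2. SNRNP200 was at 0.26 ± 0.12, tfr1a at 0.84 ± 0.27 and npsn at -0.47 ± 0.37, none of them called. Without replicate 2 of the sibling CA-Stat3 group, 3 genes were called, SIK1 among them (-1.05, edgeR BH-adjusted p = 0.0382), and without replicate 2 of the wildtype CA-Stat3 group 1 gene was called. As lists, erythroid (median 0.82, 15 of 25 higher adjusted over the list alone), yolk and liver (2.02, 11 of 19), neural (0.67, 8 of 40), muscle (1.31, 0 of 36), pronephric (0.41, 1 of 20), cell cycle (0.15, 1 of 52) and spliceosome genes (0.09, 0 of 99) tested upward. Pan-endothelial (-0.37), venous (-0.38), arterial (-0.26), haemogenic (-0.29), macrophage and neutrophil (-0.40), immediate-early and heat-shock (-0.30) and STAT3 target genes (-0.12) tested downward. These 14 lists were called by camera with BH-adjusted p of at most 0.0205, and again their adjusted p = 0.268 to 0.596 with an estimated correlation. Replicate 2 of the sibling WT-Stat3 group carried much of some of these medians, which without it were 0.30 for yolk and liver, -0.36 for muscle, 0.04 for cell cycle and -0.17 for haemogenic genes. Yolk and liver means were 2.25 to 3.14 log2 CPM in 3 sibling libraries, but 0.86 and 0.84 in the other 2, below the 0.96 to 1.47 of the wildtypes. The muscle median was 0.56 without replicate 3 of the sibling CA-Stat3 group. Macrophage and neutrophil genes were at -0.11 without replicate 2 of the wildtype WT-Stat3 group and -0.61 without replicate 2 of the sibling CA-Stat3 group. Pronephric genes were at 0.26 without replicate 1 of the sibling WT-Stat3 group and 0.22 without replicate 2 of the wildtype CA-Stat3 group. STAT3 target genes were at -0.06 without replicate 1 of the wildtype WT-Stat3 group, and at -0.07 and -0.19 without replicates 1 and 2 of the sibling CA-Stat3 group.

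The mutant difference was also taken within each construct, from sets of libraries with none in common, to ask whether it was present with either form of Stat3. RSPO1 was among the genes that rose most with both. It had only 6 counts over the 2 wildtype WT-Stat3 libraries and 9 over the 3 wildtype CA-Stat3 libraries, so the size of its rise is uncertain. With WT-Stat3, edgeR with BH adjustment called 2177 genes, 1106 higher and 1071 lower. The largest increases were RSPO1 (5.03 ± 0.85), abcc6a (4.70 ± 1.07) and RNF224 (4.52 ± 0.70). With 2 and 3 counts over the wildtype libraries, the last 2 had pooled ratios of 31.1 and 26.3 (95% counting intervals 7.9 to 269 and 8.34 to 133). shtn2, fcer1g and crybb1l1 had 0 counts in both mutant libraries and were at least 18.3-, 14.3- and 13-fold lower, taking 3 counts over the group as the floor. This count rested on single libraries, being 662 without replicate 2 of the mutant group, 1003 without replicate 1 and 751 without replicate 2 of the wildtype group, and 903 without both outlying libraries (replicate 2 of the mutant WT-Stat3 group and replicate 3 of the sibling CA-Stat3 group), a setting chosen after seeing the data. abcc6a was not called without replicate 1 of the wildtype group (3.59). shtn2 was not called without replicate 2 of the wildtype group or replicate 1 or 2 of the mutant group (edgeR BH-adjusted p = 0.0941, 0.0879 and 0.12). fcer1g was not called without replicate 2 of the wildtype or of the mutant group (0.0511 and 0.0576), and crybb1l1 without replicate 1 of the wildtype group or replicate 1 or 2 of the mutant group (0.0704, 0.0535 and 0.0692). With CA-Stat3, 2646 genes were called, 1308 higher and 1338 lower. The count was 1383 without replicate 2 and 1612 without replicate 3 of the mutant group, and 1651 without replicate 2 and 1611 without replicate 3 of the wildtype group. ARMC2 (4.54 ± 0.74, with 3 counts over the wildtype libraries and a pooled ratio of 26.2, 95% counting interval 8.53 to 131), ATXN1 (4.41 ± 0.36) and RSPO1 (4.29 ± 0.69) had the largest increases. crybb1l1 (-5.64 ± 0.92), gprin3b (-5.56 ± 1.08) and CRYBA4 (-4.36 ± 1.04) had the largest decreases, but with only 2, 1 and 2 counts over the 3 mutant libraries their order is uncertain. Their pooled ratios were 59.8, 63.8 and 23.5 (95% counting intervals 16.3 to 498, 11.1 to 2550 and 6.26 to 199), CRYBA4 losing its call without replicate 2 of the mutant group (-3.95).

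Gene groups were also compared within the 2 constructs. Spliceosome medians were 0.72 with WT-Stat3 (50 higher, 3 lower of 99) and 0.85 with CA-Stat3 (56 higher, 1 lower). Macrophage and neutrophil medians were -2.13 (21 of 35 lower) and -1.79 (20 lower), and mesenchymal medians were -1.07 (10 of 41 lower) and -1.10 (21 lower). Camera called 11 lists in each construct, with adjusted p = 0.225 to 0.74 and 0.0522 to 0.761 with an estimated correlation. Across 18020 genes, which are not independent replicates, the mutant log2 fold changes in the 2 constructs correlated at r = 0.635 and rho = 0.648, with a slope of 0.474. Of 1324 genes called in both, 1323 had the same direction, 713 higher and 610 lower, where independent lists of these sizes would share 80.3 and 79.5. The correlation was 0.411 without replicate 1 of the mutant WT-Stat3 group. Sibling changes with WT-Stat3 correlated with mutant changes with CA-Stat3 at 0.08, and at -0.004 without replicate 1 and 0.13 without replicate 2 of the sibling WT-Stat3 group, 0.121 without replicate 1 of the wildtype CA-Stat3 group and 0.021 without replicate 1 of the mutant CA-Stat3 group. Sibling changes with CA-Stat3 correlated with mutant changes with WT-Stat3 at 0.107, and at 0.052 without replicate 2 of the wildtype WT-Stat3 group, -0.003 without replicate 1 of the mutant WT-Stat3 group and 0.053 without replicate 3 of the sibling CA-Stat3 group.

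**Figure D3:**
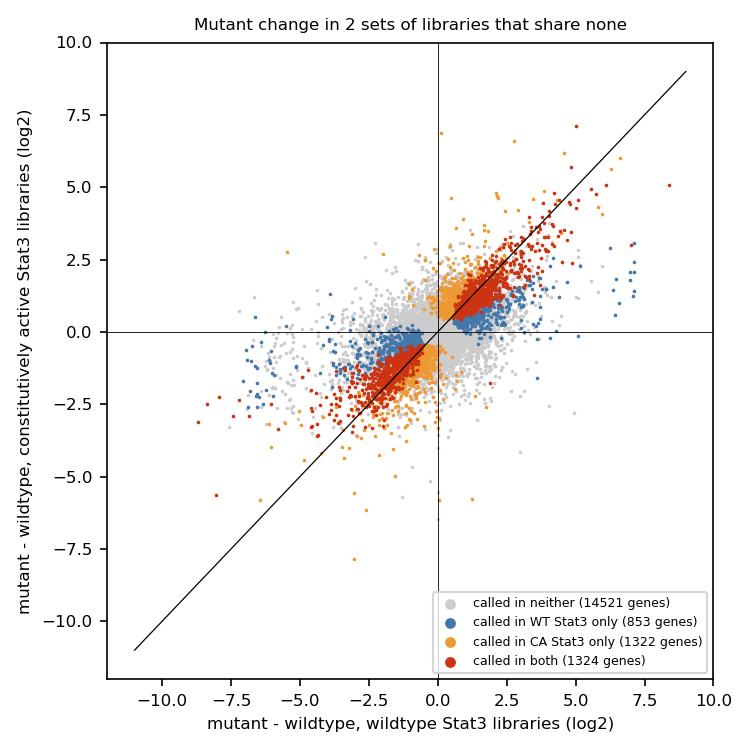
Mutant minus wildtype log2 fold change in WT-Stat3 libraries (x axis) against CA-Stat3 libraries (y axis) for 18020 genes, coloured by whether a gene was called in neither, 1 or both, with the line of equal change. Nearly all of the 1324 genes called in both lie in the lower left or upper right quadrant.

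The effect of constitutive activity was the CA-Stat3 minus WT-Stat3 difference averaged over genotypes. edgeR called no single gene, and as lists endothelial genes tested downward and genes of other cell types upward by camera, except yolk and liver genes (median -0.28, camera BH-adjusted p = 0.185). Among the endothelial lists, haemogenic endothelium and blood stem cell genes were not called (list mean 0.03 ± 0.09, SE across libraries). The list calls made by camera were lost with an estimated correlation (adjusted p = 0.403 to 0.727 with an estimated correlation), by fry, and by an exact permutation test across libraries (smallest adjusted p = 0.15). The angiopoietin receptor tek was at -0.66 ± 0.13, stab2 at -0.57 ± 0.12, the Notch ligand dll4 at -0.75 ± 0.18 and cdh5 at -0.37 ± 0.14, while lyz was at 1.0 ± 0.29, hbae3, an embryonic globin, at 0.76 ± 0.28, and the neuronal gene ELAVL3 at 0.73 ± 0.26. The 2 genes for SOCS3 were at 0.32 ± 0.13 (ENSDARG00000026611) and 0.19 ± 0.25 (ENSDARG00000025428), and the 37 STAT3 target and feedback genes had a median of -0.05 with 0 called adjusted over the list alone (camera BH-adjusted p = 0.0723). edgeR with BH adjustment called 0 of 18020 genes, with 2286 at an unadjusted p under 0.05; DESeq2 called 133, 51 higher and 82 lower, and limma-voom 1. With no filter on expression, edgeR called 386 genes, of which 383 pass the filter, and with the replicate block it called 28. The smallest adjusted p was 0.0654, for the kinase SIK1 (-0.83 ± 0.12). Without replicate 1 of the mutant WT-Stat3 group, edgeR called 194 genes, among them tek (-0.67), stab2 (-0.62), lyz (1.67) and SIK1 (-0.83). SIK1 was also called without replicate 2 of the wildtype CA-Stat3 group (-0.92) and without replicate 2 (-0.89) or 3 (-0.81) of the sibling CA-Stat3 group. The counts were 1, 1 and 3 genes there, and 1 gene without replicate 2 of the sibling WT-Stat3 group.

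As lists, pan-endothelial (median -0.36, 6 of 32 lower adjusted over the list alone), arterial (-0.25, 5 of 32), venous and lymphatic (-0.38, 11 of 19), Notch (-0.08, 1 of 40) and immediate-early and heat-shock genes (-0.13, 1 of 49 higher) tested downward. Muscle (1.02, 0 of 36), macrophage and neutrophil (0.48, 4 of 35 higher), epidermal (0.38, 0 of 31), erythroid (0.35, 5 of 25), neural (0.35, 1 of 40), pronephric (0.28, 0 of 20), ribosomal (0.19, 0 of 88), mesenchymal (0.17, 0 of 41), mitochondrially encoded (0.15, 0 of 13) and spliceosome genes (0.06, 0 of 99) tested upward. Camera called these 15 lists with BH-adjusted p of at most 0.0354, fry called 0, and their adjusted p = 0.403 to 0.727 with an estimated correlation. Across libraries, the exact permutation test over 1000 splits within genotype gave a smallest adjusted p of 0.15 for any list. Replicates lay far apart for some lists, so the muscle and the macrophage and neutrophil values can move with single libraries. Muscle means were 2.73 and 6.13 log2 CPM in the sibling WT-Stat3 libraries. Macrophage and neutrophil means were 3.48 and 2.17 log2 CPM in the mutant WT-Stat3 libraries.

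Within single genotypes, edgeR with BH adjustment called 0 genes for CA-Stat3 minus WT-Stat3 in wildtypes (725 at an unadjusted p under 0.05; DESeq2 3, limma-voom 0), 0 in siblings (753; DESeq2 1, limma-voom 0) and 0 in mutants (1845; DESeq2 56, limma-voom 0). In mutants, 536 were called without replicate 1 of the WT-Stat3 group, and in wildtypes 1 was called without replicate 2 of the CA-Stat3 group. The clearest list was ribosomal protein genes in mutants, with a median of 0.58 and 60 of 88 higher adjusted over the list alone (camera BH-adjusted p = 9.16e-33, adjusted p = 0.723 with an estimated correlation). Camera called 12 lists in wildtypes (adjusted p = 0.141 to 0.763 with an estimated correlation), 9 in siblings (adjusted p = 0.502 to 0.697 with an estimated correlation) and 11 in mutants (adjusted p = 0.723 to 0.9 with an estimated correlation). The count in mutants was 4 without replicate 2 of the mutant WT-Stat3 group and 7 without replicate 1 of the mutant CA-Stat3 group. Pan-endothelial medians were -0.43, -0.53 and -0.16 in wildtypes, siblings and mutants. In mutants only replicate 1 of the CA-Stat3 group lay below the WT-Stat3 libraries (list means 6.47, 6.98 and 7.12 log2 CPM against 7.06 and 6.98). In siblings replicate 3 of the CA-Stat3 group was the lowest (6.63, 6.66 and 5.87 against 7.03 and 6.81).

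Whether the construct changed the mutant difference was tested by the interaction. edgeR with BH adjustment called 0 genes (929 at an unadjusted p under 0.05; DESeq2 1, limma-voom 0), with a median SE of 0.549 on the log2 scale, and 59 without replicate 1 of the mutant WT-Stat3 group and 1 without replicate 2 of the wildtype CA-Stat3 group. Ribosomal protein genes were the 1 list of 23 called by camera, with a median of 0.54 (RPL12 at 0.86 ± 0.25, camera BH-adjusted p = 1.47e-26, adjusted p = 0.55 with an estimated correlation). For siblings the interaction gave 0 genes (212 at an unadjusted p under 0.05; DESeq2 0, limma-voom 0) and 1 list, erythroid genes, with a median of -0.46 (camera BH-adjusted p = 0.000404, adjusted p = 0.997 with an estimated correlation). Both list counts rose without most single libraries, but stayed at 1 without replicate 2 of the mutant CA-Stat3 group for mutants, and without replicate 1 or 3 of the wildtype CA-Stat3 group for siblings. In the mutant interaction camera called 7 lists without replicate 1 and 6 without replicate 2 of the mutant WT-Stat3 group, and 7 without replicate 1 and 2 without replicate 3 of the mutant CA-Stat3 group. It called 2 without replicate 1 and 5 without replicate 2 of the wildtype WT-Stat3 group, and 4, 7 and 3 without replicates 1, 2 and 3 of the wildtype CA-Stat3 group. In the sibling interaction it called 3 without replicate 1 and 7 without replicate 2 of the sibling WT-Stat3 group, and 4, 5 and 5 without replicates 1, 2 and 3 of the sibling CA-Stat3 group. It called 2 without replicate 1 and 3 without replicate 2 of the wildtype WT-Stat3 group, and 3 without replicate 2 of the wildtype CA-Stat3 group.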

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

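The tests of depth, of 1 library and of cell share for spliceosome genes, and all tests for macrophage, mesenchymal and neural genes, were chosen only after the result was seen, as were the settings that leave out both outlying libraries, thin the counts, or leave out single libraries in list tests, and the demand that all lists of other cell types be higher with CA-Stat3.

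The interaction of construct with genotype differed for 2 lists. Ribosomal protein genes had a mutant change of -0.56 with WT-Stat3 and 0.02 with CA-Stat3 as list means, and their median interaction was 0.54 (camera BH-adjusted p = 1.47e-26, adjusted p = 0.55 with an estimated correlation). Across libraries the mean interaction was 0.58 ± 0.19 (exact permutation p = 0.08 over 100 splits, the smallest possible being 0.02), and the median was 0.78 without replicate 1 and 0.40 without replicate 2 of the mutant WT-Stat3 group. Erythroid genes had a median interaction of -0.46 in siblings (camera BH-adjusted p = 0.000404, adjusted p = 0.997 with an estimated correlation), with a mean across libraries of -0.48 ± 0.71 (exact permutation p = 0.53). That median was -0.13 without replicate 3 and -0.81 without replicate 1 of the sibling CA-Stat3 group, -0.26 without replicate 1 of the sibling WT-Stat3 group, -0.27 without replicate 1 of the wildtype WT-Stat3 group, and -0.20 and -0.72 without replicates 2 and 3 of the wildtype CA-Stat3 group.

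Spliceosome genes were higher in mutants, with a median of 0.82, although the list was not called with an estimated correlation (adjusted p = 0.0869 with an estimated correlation). Lower depth of the mutant libraries is argued against, since 62 members were still called higher after thinning to the shallowest library, and replicate 2 of the mutant WT-Stat3 group alone is argued against, since the median was 0.85 in CA-Stat3 libraries. The expression level of the genes is argued against by a highest median of 0.17 among 10000 random lists matched on it, and a higher share of endothelial cells by a mutant minus wildtype change of the spliceosome mean that exceeded that of the pan-endothelial mean by 1 ± 0.18. A response to the loss of sf3b1 function may explain the rise, as a hypothesis found and tested on the same data, and whether it reflects transcription, RNA stability or retained transcripts was not tested.

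Macrophage and neutrophil, mesenchymal and neural genes were lower in mutants by camera (adjusted p = 0.162, 0.162 and 0.692 with an estimated correlation). A higher share of endothelial cells in the mutant sort would, as the only cause, lower the markers of all other types alike. Against wildtypes, erythroid genes argue against it as the only cause, with a mean 1.13 ± 0.36 higher (hbae3 at 347 ± 152 CPM in wildtypes and 615 ± 366 CPM in mutants, SD, n = 5 each). Erythroid genes also tested higher in siblings than in wildtypes by camera, so their rise was not particular to mutants. Against siblings, where pan-endothelial genes tested higher in mutants by camera, this explanation was not tested. Replicate 2 of the mutant WT-Stat3 group alone is argued against, since the list median nearest to 0 was still -0.67 in CA-Stat3 libraries, although without it the neural calls fell from 15 to 3. Fewer cells of these types among the sorted cells may explain the pattern. Of the 33, 37 and 34 members with an average log2 CPM of at least 1, 97%, 94.6% and 85.3% lay below 0. Abundant markers fell unequally, steeply for npsn, lyz and COL1A1 (588 ± 205 to 101 ± 29.7 CPM, SD, n = 5 each). The mesenchymal list member POSTN fell only from 363 ± 59.3 to 282 ± 64.6 CPM. The neural list member tubb2b fell from 426 ± 40.2 to 310 ± 32.2 CPM (SD, n = 5 each). These bulk counts do not separate fewer cells from less expression per cell. The kdrl sort should have removed most cells of these types, but their transcripts were not rare. In wildtypes npsn had 527 ± 151 and lyz 511 ± 133 CPM (SD, n = 5 each), beside 522 to 821 CPM for kdrl. How many such cells remained was not measured.

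Genes of other cell types tested higher and endothelial genes lower with CA-Stat3 by camera. However, yolk and liver genes did not test higher (median -0.28), and haemogenic endothelium genes did not test lower (list mean 0.03 ± 0.09, SE across libraries). With an estimated correlation no list was called (adjusted p = 0.403 to 0.727 with an estimated correlation). Both outlying libraries alone are argued against, since the pan-endothelial median was -0.28 without them. A lower share of endothelial cells in the CA-Stat3 sorts was neither shown nor excluded. No list of the 8 other cell types departed from the mean of the rest by more than 1.71 standard errors (muscle genes, 0.80 ± 0.47), but yolk and liver genes departed by -0.56 ± 0.38, so these errors are too wide to show that the lists moved alike. An effect of Stat3 activity on endothelial identity stays open too and was not tested apart from this share.

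Other splits of the libraries asked whether chance could give as large a result. For mutant against wildtype chance was unlikely for the 5169 genes (1 of 60 splits, highest other 4) and the cross-construct correlation of 0.635 (1 of 60, highest other 0.433). No share under 1 of 60 was possible. Chance was not excluded for the number of 14 lists (4 of 60, highest other 15). List by list, the exact permutation test over 120 splits had a smallest possible p of 0.0167. Spliceosome, macrophage and neutrophil, mesenchymal, neural, erythroid, muscle, STAT3 target and stress response genes reached it (adjusted p = 0.0383). Venous (0.0639), immediate-early (0.0885), mitochondrially encoded (0.128), epidermal (0.144) and ribosomal genes (0.277) were not called by it. For mutant against sibling chance was unlikely for the 4729 genes (1 of 60, highest other 327) but was not excluded for the 12 lists (11 of 60, highest other 15). For sibling against wildtype it was not excluded for the 14 lists (6 of 60, highest other 17). For the constructs 4 of 100 splits drawn from 1000 gave the 15 lists, the highest other split also giving 15. That share is under 0.05, but the exact permutation test over all 1000 splits gave a smallest adjusted p of 0.15 for any list, so chance was not excluded for single lists. The 0 genes called by edgeR for sibling against wildtype (1712 at an unadjusted p under 0.05, DESeq2 12, limma-voom 0) and for the constructs (2286, DESeq2 133, limma-voom 1) could not be tested this way. Every split calls at least 0 genes, so 60 of 60 and 100 of 100 were as large by design. The highest other splits called 4 and 56 genes, the 56 in 1 split only. For mutant against wildtype with CA-Stat3 the 10 splits were too few, with 2646 genes against 0 in the highest other split and 11 lists against 13.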

How the results depend on the processing

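Leaving out both outlying libraries, thinning, leaving out the 3 most abundant rows, and leaving out single libraries in list tests and correlations were chosen after seeing the data. Counts of genes below are by edgeR unless another tool is named, and the cause was not tested for any value that moved, except that smaller fits hold fewer libraries.

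The mutant averages kept their count within 1.5 times under all settings run, with 3812 to 5343 against wildtypes and 3252 to 5050 against siblings when single libraries were left out, and DESeq2 shared 5114 of its 5502 genes and 4678 of its 5115 with edgeR. Within WT-Stat3 the 2177 genes became 903 without both outlying libraries (61.1% of them higher, against 50.8%), 998 with limma-voom, 961 with own libraries only, and 662 to 2730 with single libraries left out. Within CA-Stat3 the 2646 genes became 4018 with limma-voom and 1383 to 2752 with single libraries left out. Siblings against wildtypes had 258 genes with no filter, 12 with DESeq2 and 0 to 3 with single libraries left out. The average construct effect had 386 genes with no filter (383 of them among the genes that pass it), 133 with DESeq2, which gave 4894 genes no adjusted p, 1 with limma-voom, 1 after thinning to the shallowest library and 0 to 194 with single libraries left out. Construct effects within genotypes had 13 genes with no filter and 3 with DESeq2 in wildtypes (0 to 1 with single libraries left out), 8 and 1 in siblings (0 to 0), and 110 and 56 in mutants (0 to 536), where DESeq2 gave 16770 genes no adjusted p. The mutant interaction had 8 with no filter, 1 with DESeq2 and 0 to 59 with single libraries left out, and the sibling interaction 1 with no filter and 0 to 0.

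Replicate numbers were tested as a replicate block. Of 33 same-numbered pairs of libraries, 9 had deviations correlated above 0.1 (range -0.15 to 0.34, median 0.08). Among CA-Stat3 libraries these correlations were 0.1 to 0.2 for replicate 1, 0.18 to 0.27 for replicate 2 and -0.01 to 0.09 for replicate 3. Sibling and mutant WT-Stat3 libraries of the same number were at -0.15 and those of unlike number at 0.15. The 2 libraries of a WT-Stat3 group deviate from their mean equally in opposite directions. Such values therefore repeat, and the 33 pairs are not independent. Yet 12 of 15 libraries correlated best with their own number, a hint from the data and not the design. Pairing by number was thus neither shown nor excluded, and the main counts assume that there is none. With the replicate block 2 genes were called for siblings against wildtypes, 28 for the average construct effect and 7 for the construct in mutants, and the other counts stayed within 1.5 times.

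List tests called 0 lists in all 11 comparisons with an estimated correlation. Fry called 0 for siblings against wildtypes, the average construct effect, the construct in wildtypes and in siblings and both interactions, 6 for mutants with CA-Stat3 and 1 for the construct in mutants. Without both outlying libraries camera called 6 lists for the construct in mutants, 7 in the mutant interaction and 5 in the sibling interaction, after thinning to the shallowest library 6 and 2 in the interactions, and with the 3 most abundant rows left out 3 in the mutant interaction. With single libraries left out camera called 12 to 15 lists for mutants and 13 to 16 for siblings against wildtypes, 7 to 14 for mutants against siblings, 13 to 16 for the average construct effect, 10 to 12 and 9 to 14 for mutants with WT-Stat3 and CA-Stat3, 9 to 14, 7 to 13 and 4 to 11 for the construct in wildtypes, siblings and mutants, and 1 to 7 in each interaction.

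The cross-construct correlation of mutant changes was 0.827 at an average log2 CPM of at least 3, 0.722 with a prior count of 5, 0.504 without both outlying libraries and 0.411 to 0.642 with single libraries left out. Sibling changes with WT-Stat3 against mutant changes with CA-Stat3 gave 0.192 at that expression, 0.125 with that prior count and -0.004 to 0.13 with single libraries left out. The converse gave 0.206 at that expression, 0.045 without both outlying libraries and -0.003 to 0.144 with single libraries left out. The lowest value changed sign in both, without replicate 1 of the sibling WT-Stat3 group and without replicate 1 of the mutant WT-Stat3 group.

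SF3B1 was called in mutants with each library left out, at -1.06 to -0.93 against wildtypes and -0.84 to -0.71 against siblings. Of 151 tests of named genes, none changed sign among called values, and RLE, the stricter filter and leaving out the 3 most abundant rows left all 151 on the same side of the threshold. DESeq2 added 5 calls, the replicate block 3, and no filter 12 while losing 1, limma-voom added 1 and lost 7, thinning added 1 and lost 1, and leaving out both outlying libraries lost 3. With single libraries left out, 10 tests gained a call and 32 lost it while 1483 stayed on the same side of the threshold. Thinning to the shallowest library gave 2011 genes within WT-Stat3 in place of 2177. In simulated counts of 17510 genes for mutants with WT-Stat3 edgeR recovered 4.48% of 2-fold and 50.8% of 4-fold changes.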

Other observations

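The tests of symbol families were chosen only after the mutant result was seen, and the 2 hypotheses on siblings and constructs were written before their tests were run.

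Mutants had higher transcripts of the polr family of RNA polymerase subunits, the ddx helicases and the utp and prpf families, and lower transcripts of collagens and of the mfap family. Genes were grouped by the leading letters of their symbols into 264 families of at least 8 members, and each was compared with all 14248 tested genes whose symbol has such a prefix, of which 13.8% were higher and 15.4% lower in mutants (one-sided Fisher's exact test, BH over 528 tests). Of 31 polr genes, which encode RNA polymerase subunits, 22 were higher and 1 lower (adjusted p = 3.39e-10). POLR2B rose by 1.40 ± 0.15 and POLR1B by 1.77 ± 0.21, while POLR2A, the largest subunit of RNA polymerase II, fell by 0.58 ± 0.15. Of 32 ddx helicase genes 17 were higher and 0 lower (adjusted p = 2.9e-05), with DDX56 at 1.60 ± 0.18, and of 10 utp genes of the small subunit processome 8 were higher and 0 lower (adjusted p = 0.000345), with UTP4 at 1.24 ± 0.15 and UTP15 at 1.56 ± 0.21. Of 11 prpf genes, 9 of them also in the fixed lists, 8 were higher (adjusted p = 0.000972), with PRPF3 at 2.78 ± 0.16.

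Of 51 genes with the col prefix, 15 of them also in the fixed lists, 28 were lower and 2 higher (adjusted p = 2.11e-08), and 17 were lower without replicate 2 of the mutant WT-Stat3 group. COL5A2 fell by 2.42 ± 0.23 and col11a1b by 1.29 ± 0.21. Of 14 mfap genes 10 were lower (adjusted p = 0.000345), with mfap4.8 at -1.88 ± 0.26. Of these 10, 9 were mfap4 genes, which mark macrophages in zebrafish, and 5 of the 14 were in the fixed lists, so this family is not apart from the macrophage and neutrophil list. These 6 families were called in each of the 22 other settings run for families, RLE size factors included. Another 9 families were called but lost under at least 1 setting, namely eif, mrpl, trmt, nup, lsm and timm among the higher and hist, pou and aldh among the lower. The eif call was lost without replicate 2 of the wildtype WT-Stat3 group (14 of 63 higher, adjusted p = 0.056) and stood at 24 of 63 with all libraries (adjusted p = 0.000184). Genes of a family are not independent, so these p-values overstate the evidence.

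The first hypothesis was that siblings carry a weaker form of the mutant profile. Genes called in mutants with 1 construct were scored by sign in the siblings with the other construct, so that no library was shared, and the mean signed log2 changes were 0.155 and 0.142, or 0.149 together. Of 120 splits of sibling and wildtype libraries within construct, 2 gave a mean as large, the highest other being 0.157 (exact one-sided permutation p = 0.0167, the smallest possible being 0.00833). A weaker form of the mutant profile in siblings may account for this. Over all genes, however, sibling and mutant changes across constructs correlated only at r = 0.08 and 0.107 (rho = 0.146 and 0.141). With single libraries left out, r was -0.004 and -0.003 at the lowest. Sibling changes with WT-Stat3 and with CA-Stat3 correlated with each other at r = 0.356, a value that was not compared with other splits. Of the lists called in both comparisons, neural (0.67 against -0.57) and muscle medians (1.31 against -0.96) went opposite ways. The sibling muscle median turned negative without replicate 2 of the sibling WT-Stat3 group. Erythroid, macrophage and neutrophil, venous, spliceosome, immediate-early and heat-shock and STAT3 target medians had the same sign in siblings and mutants. A cell makeup shared by siblings and mutants stays open and was not tested.

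Another hypothesis was that constitutively active Stat3 lessens the mutant change. Among the 14 lists called for mutants, the smallest adjusted exact permutation p for a difference between constructs was 0.56, shared by STAT3 target genes (mutant change -0.49 with WT-Stat3 and -0.29 with CA-Stat3) and ribosomal protein genes (-0.56 and 0.02). The groups of 2 and 3 libraries were too small to decide, so this could be neither shown nor excluded.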
